A study of Macaca fascicularis with 44 samples.

How the data were processed

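RNA-seq libraries from 4 brain regions of female cynomolgus macaques (Macaca fascicularis) were compared between animals given betamethasone and animals given saline. The deposited files hold whole-number read counts per gene for each library, with an unstranded count and a count for each strand. The reads were processed with STAR, per the submitters' processing notes. Its version, the genome build and the annotation release are not given in the sources used here. Each deposited table lists 17452 gene rows with 17293 different Ensembl-style gene identifiers. The tables do not pair the identifiers with gene names, and 0 identifiers matched the gene table used here, so genes are given by identifier and without position. At most 2 identifiers in each direction are named per comparison.

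The strand column whose gene total exceeded the other by at least 2 times in every library was used, as set before the data were examined; the ratio was 51.7 to 79.3. The opposite strand took 1.25% to 1.90% of the reads, so reads from a gene and an antisense partner were kept apart. A total of 139 identifiers stood on more than 1 row (298 rows, 1.47% of gene reads), and their counts were summed. Multimapping reads were listed as 0 in every table, so the counts leave open how reads shared between near-identical gene copies were treated. The rows that name no gene stayed out of library sizes and tests. Of all reads, 11.0% to 31.4% were unmapped, and of mapped reads 24.5% to 37.2% lay outside annotated genes and 0.333% to 0.455% were ambiguous.

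Depth ranged from 28449737 to 83322595 gene reads per library (median 44944904). Precision was therefore limited by the spread between libraries more than by counting for all but the genes with few reads; the biological coefficient of variation within a region was 19.0% in the anterior cingulate cortex, 23.8% in the posterior dentate gyrus, 26.9% in the anterior dentate gyrus and 29.2% in the basolateral amygdala. All 101 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 20.6 to 454), so none was counted as the same library sequenced again. This does not show that they came from different animals.

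Libraries were grouped by the region and treatment in the labels, and replicates were numbered in accession order within a group. The labels do not say whether libraries of different regions came from the same animals. Title numbers of the anterior and posterior dentate gyrus libraries were 31 apart, one for one, and this was checked as a possible pairing by correlating deviations from the group means. All 6 saline pairs correlated above the minimum of 0.1 set beforehand (0.15 to 0.66), and of all 11 pairs 9 did. The pairing was therefore used as a replicate block for the comparison of saline libraries and, as an alternative only, for the interaction of the dentate gyrus parts, and the planned test on summed counts of both dentate gyrus parts is not reported. Title numbers also run in parallel in the basolateral amygdala and anterior cingulate cortex. Their offsets from the anterior dentate gyrus are multiples of 31. After a gap the offset changes by 1, down in the basolateral amygdala and up in the anterior cingulate cortex. Matched in this way, 10 sets (4 betamethasone, 6 saline) held 1 library of each region. The change by 1 was chosen so that treatments agree, so agreement in those 2 regions is no evidence for the sets. A further set, fitted by 2 libraries (anterior cingulate cortex betamethasone replicates 3 and 4), was left out. This matching was made after the correlations of libraries were seen. Over all region pairs 55 of 60 matched pairs correlated above 0.1 (-0.07 to 0.66), and in 55 of 60 the matched library of the latter region was the closest of its group. The sets are therefore a hint from the data, used as an alternative block and for joint permutation of treatment.

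Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes kept, at a threshold of 0.05. Each region was fitted alone for the effect of treatment. Differences of the treatment effect between regions were tested as interactions in a fit of all 44 libraries, which treats libraries as independent. Regions were compared in the 24 saline libraries, and the dentate gyrus value was the mean of both parts. Standard errors (SE) of log2 fold changes were taken as the size of the change divided by the square root of its F value. CPM values, the usual depth-scaled counts, were computed from the gene reads of each library. Measures of single libraries were compared by two-sided exact permutation tests. Correlations of treatment effects across genes were set against 99 regroupings with treatment permuted, jointly by title number for the dentate gyrus pair and separately otherwise, and differences of mean log2 CPM against all 210 splits of the 10 sets by one-sided exact permutation.

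The test steps were tested on simulated data with 200 changed genes, drawn from genes with an expected count above 100 per library. With that many changes the adjusted threshold is easier to reach than in data with few. The shares found may therefore be too high for the real data. In the simulated anterior cingulate cortex comparison (14476 genes), 58.2% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes were found, and in that of the basolateral amygdala (14564 genes) 14.9%, 67.2% and 98.5%. The corresponding shares were 34.3%, 73.1% and 100% in the anterior dentate gyrus (14457 genes) and 50.7%, 80.6% and 98.5% in the posterior dentate gyrus (14366 genes).

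Identifiers were named by a rule written before the data were examined. For treatment, genes past the threshold with the lowest p in each direction were named, and where fewer than 5 passed, those with the lowest p were added as not passing. For regions, genes past the threshold with the largest fold and a mean of at least 5 CPM were named. The rule asked for a gene symbol, which could not be applied, and its list was shortened to 2 in each direction. Planned tests that need gene symbols (gene lists, glucocorticoid receptor targets and cell type markers) were not run. Alternatives were other scaling factors, DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), 1 surrogate variable from sva 3.50.0, other filters and thresholds, the unstranded column and leaving out each library in turn. After the data were examined, 5 more were added: repeated identifiers kept apart, the share of mapped reads outside annotated genes as a covariate, 2 libraries left out together, the replicate block without 1 pair, and the set over 4 regions as replicate block.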

Results

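Gene expression was measured by RNA-seq in the anterior dentate gyrus (aDG) and posterior dentate gyrus (pDG) of the hippocampus, the basolateral amygdala (BLA) and the anterior cingulate cortex (ACC) of female cynomolgus macaques. The animals had received betamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, or saline. There were 44 libraries. The betamethasone groups held 5 aDG, 5 pDG, 4 BLA and 6 ACC libraries, and each saline group held 6. Median depth per group lay between 33296082 gene reads (aDG saline, range 28449737 to 71378308) and 51400244 (aDG betamethasone, range 37810604 to 83322595). The labels do not say that replicates were separate animals, so p-values measure the spread between these libraries, which may be technical.

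Expression separated the libraries first by region. The first principal component (33.6% of variance) set ACC apart from the dentate gyrus, and the second (15.1%) set BLA apart. On an axis built from genes that differed between pDG and BLA, with the pDG mean at 0 and the BLA mean at 1, the BLA libraries lay between 0.954 and 1.04 and 10 aDG libraries between 0.0864 and 0.211. The library labelled aDG saline replicate 5 lay at 1.002. In that library the median level of 17 pDG-specific genes was 3.78% of that in the other aDG libraries, and the median level of 13 BLA-specific genes was 62.8% of that in BLA libraries. BLA saline replicate 5 lay with its region on this axis (0.954), but the median level of the BLA-specific genes in it was 22.4% of that in the other BLA libraries, where the others lay between 52.2% and 110.8%. In that library the pDG-specific genes stood at 6.56% of their level in aDG, and 149 genes were at least 4-fold above every other BLA library.

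**Figure D1:**
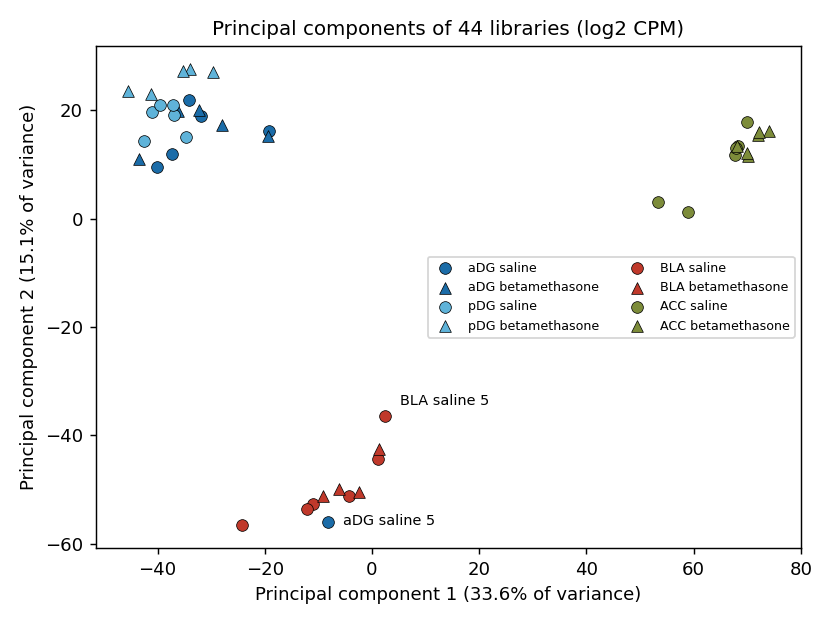
Each point is 1 of 44 libraries placed by the first (x axis, 33.6% of variance) and second (y axis, 15.1%) principal components of log2 CPM, with colour for region, circles for saline and triangles for betamethasone. ACC lies at the right, BLA at the bottom and the dentate gyrus at the upper left, with aDG saline replicate 5 among the BLA points.

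**Figure D2:**
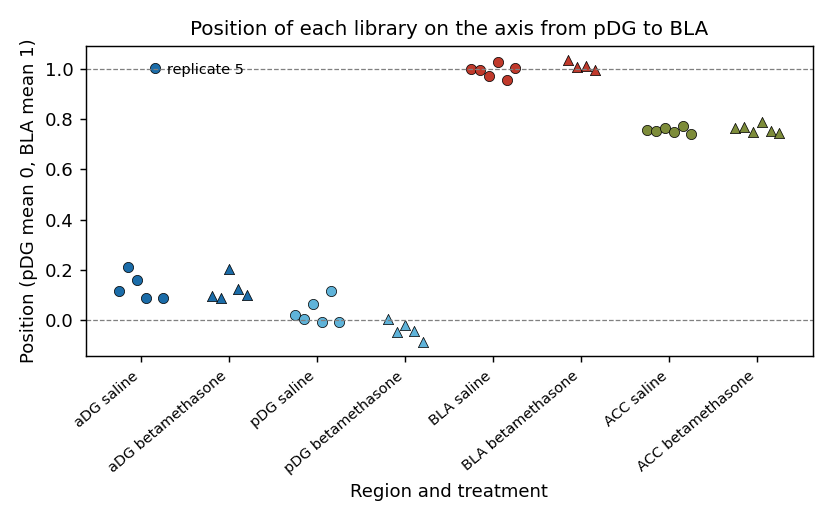
Each point is 1 library, by region and treatment (x axis), at its position on the pDG to BLA axis (y axis, no unit, dashed lines at the pDG mean of 0 and the BLA mean of 1). aDG saline replicate 5 lies at 1.002, while the other aDG libraries lie at 0.211 or lower.

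The first question was which genes differed with the glucocorticoid in each region. One identifier, ENSMFAG00000045861, was higher with betamethasone in every region. All 20 betamethasone libraries held 7.31 to 39.8 CPM of it and all 24 saline libraries 0.0215 to 3.04 CPM, and of the 14137 genes tested in all 4 regions it alone separated all libraries by treatment. That criterion pools the regions, so a gene whose level differs between regions can fail it whatever its response. In edgeR it passed the threshold in aDG, pDG and ACC but not in BLA, where DESeq2 called it (adjusted p = 0.00378). In the other direction, ENSMFAG00000036771 was lower in each region's fit, with log2 changes of -1.60 (aDG), -1.53 (pDG), -1.35 (BLA) and -1.66 (ACC), though with all libraries it passed the threshold in edgeR in ACC alone. Within aDG its highest betamethasone value lay below its lowest saline value (15.4 against 20.4 CPM). The same held within pDG (18.7 against 26.6 CPM) and ACC (4.35 against 6.25 CPM). In BLA it did not hold, because of saline replicate 5, whose 8.92 CPM lay below every betamethasone library. The other BLA saline libraries held at least 23.5 CPM and the BLA betamethasone libraries at most 16.03 CPM. Without saline replicate 5 the log2 change in BLA was -1.56. With any 1 BLA library left out the edgeR adjusted p was at least 0.149. With all libraries DESeq2 called ENSMFAG00000036771 in aDG (adjusted p = 1.35e-07), pDG (3.54e-08) and ACC (1.51e-06) but not in BLA (0.0691). For neither identifier did the size of the change differ detectably between regions (edgeR interaction adjusted p = 0.9999 for both). That fit treats libraries as independent, which can give too large a p where regions share animals, so equal changes are not shown.

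**Figure D3:**
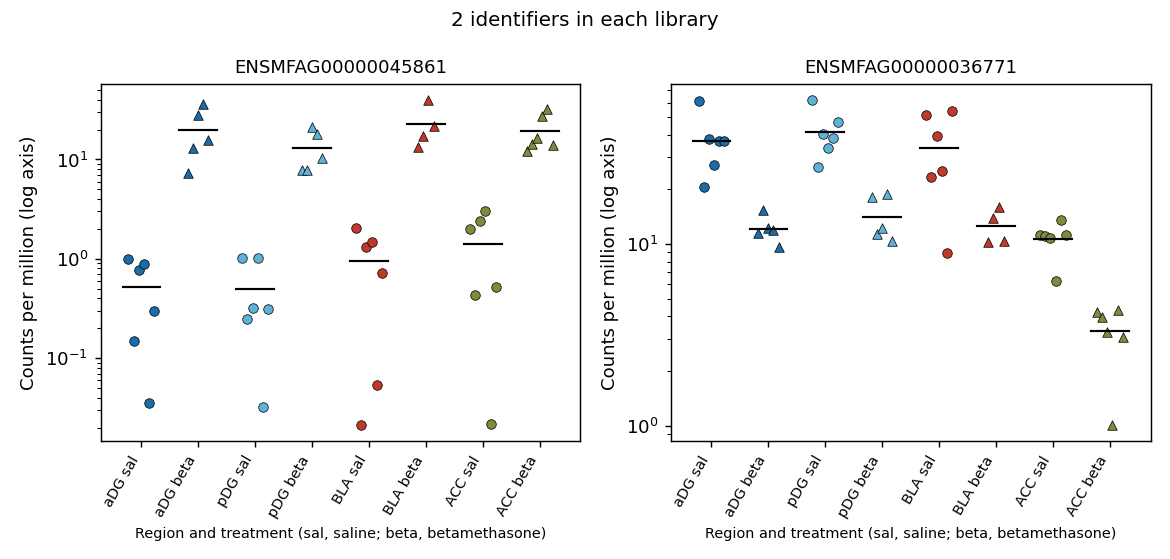
CPM of ENSMFAG00000045861 (left) and ENSMFAG00000036771 (right) on log axes in each library by region and treatment, with circles for saline, triangles for betamethasone and a line at each group mean. The 20 betamethasone libraries lie at 7.31 CPM or higher for the first identifier and the 24 saline libraries at 3.04 CPM or lower.

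In aDG, 1 of 14511 genes tested passed, and it was higher with betamethasone. ENSMFAG00000045861 averaged 19.9 ± 11.6 CPM (SD, n = 5) with betamethasone and 0.520 ± 0.407 CPM (SD, n = 6) with saline, a log2 change of 5.21 ± 0.60 (SE; edgeR quasi-likelihood adjusted p = 0.0126). The next identifiers by p did not pass. ENSMFAG00000036771 stood at 12.2 ± 2.11 against 36.7 ± 13.7 CPM (edgeR adjusted p = 0.0670), ENSMFAG00000042464 at 24.04 ± 4.09 against 40.8 ± 3.62 CPM (edgeR adjusted p = 0.0670) and ENSMFAG00000001866 at 3.61 ± 0.886 against 1.199 ± 0.386 CPM (edgeR adjusted p = 0.112). At an unadjusted p under 0.05 there were 538 genes (3.71%), and DESeq2 called 36. The call was lost without betamethasone replicate 3, saline replicate 3 or saline replicate 6 (0 genes each), where the log2 change stayed at 5.05, 5.32 and 5.10 (edgeR adjusted p = 0.0557, 0.0573 and 0.0669). Further, 2 genes passed without saline replicate 2 or 4, and 1 passed without saline replicate 5, the library that lies with BLA.

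In pDG, 1 of 14427 genes passed, again ENSMFAG00000045861. It averaged 13.0 ± 6.11 CPM (SD, n = 5) with betamethasone and 0.492 ± 0.421 CPM (SD, n = 6) with saline, a log2 change of 4.71 ± 0.59 (SE; edgeR adjusted p = 0.0238). The next identifiers did not pass. ENSMFAG00000036771 stood at 14.2 ± 3.94 against 41.3 ± 12.2 CPM (edgeR adjusted p = 0.0626), ENSMFAG00000033363 at 21.4 ± 2.45 against 42.9 ± 12.5 CPM and ENSMFAG00000000805 at 5.28 ± 1.32 against 1.82 ± 0.690 CPM (edgeR adjusted p = 0.189 for both). At an unadjusted p under 0.05 there were 1258 genes (8.72%), and DESeq2 called 82. The call was lost without any 1 of betamethasone replicates 2, 3, 4 and 5 or saline replicates 2 and 3 (0 genes each), where the log2 change stayed between 4.47 and 4.84 (edgeR adjusted p from 0.0566 to 0.123). In contrast, 2 genes passed without betamethasone replicate 1, 5 without saline replicate 4 and 7 without saline replicate 6, in which 31.4% of reads were unmapped.

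In BLA, 0 of 14644 genes passed in edgeR, with 4 betamethasone libraries. The lowest adjusted p was 0.457, 1493 genes (10.2%) had an unadjusted p under 0.05, and DESeq2 called 73 genes (7 higher, 66 lower) and limma voom 0. ENSMFAG00000045861 stood at 23.0 ± 11.8 CPM (SD, n = 4) with betamethasone and 0.944 ± 0.821 CPM (SD, n = 6) with saline, a log2 change of 4.69 ± 0.81 (SE; edgeR adjusted p = 0.457). The same adjusted p was found for ENSMFAG00000031417 (145.0 ± 14.1 against 112.4 ± 8.08 CPM), ENSMFAG00000036856 (7.98 ± 0.988 against 16.9 ± 4.25 CPM) and ENSMFAG00000042278 (17.5 ± 2.99 against 31.2 ± 3.42 CPM). Without saline replicate 5, the library with many genes of its own, 0 genes passed as well.

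ACC held the most genes past the threshold. It also had the most betamethasone libraries and the lowest biological coefficient of variation (19.0%, against 23.8% to 29.2% in the other regions). The count alone therefore does not show a larger response in ACC. Of 14543 genes tested, 48 passed, 30 higher and 18 lower with betamethasone. The median size of the change was 1.65-fold, and 13 genes changed at least 2-fold. ENSMFAG00000003719 rose from 481.5 ± 46.2 to 760.0 ± 27.96 CPM (SD, n = 6 each), a log2 change of 0.68 ± 0.07 (SE; edgeR adjusted p = 0.000872), and ENSMFAG00000008415 from 93.0 ± 9.86 to 143.1 ± 11.9 CPM (edgeR adjusted p = 0.00728). ENSMFAG00000045090 fell from 162.6 ± 20.6 to 98.7 ± 9.43 CPM, a log2 change of -0.69 ± 0.09 (SE; edgeR adjusted p = 0.00878), and ENSMFAG00000037846 from 3.91 ± 0.660 to 1.62 ± 0.352 CPM (edgeR adjusted p = 0.0187). ENSMFAG00000045861 (log2 change 3.81 ± 0.59, SE) and ENSMFAG00000036771 (-1.66 ± 0.27, SE) also passed (edgeR adjusted p = 0.0201 for both).

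In ACC, betamethasone replicates 3 and 4 fitted the same title-number set, and whether they came from the same animal was not tested. The ACC count depended on single libraries and on the method. It was 11, 23, 28, 17 and 25 without betamethasone replicate 1, 2, 4, 5 or 6, 206 without saline replicate 1 and 3 without saline replicate 2, and DESeq2 called 557 genes. Without saline replicate 2 ENSMFAG00000037846, ENSMFAG00000045861 and ENSMFAG00000036771 lost their calls (edgeR adjusted p = 0.0519, 0.0572 and 0.0661), with log2 changes of -1.21, 3.62 and -1.65, and the last also did without betamethasone replicate 6 (-1.65, edgeR adjusted p = 0.0532). With upper-quartile scaling it was 39 (20 higher, 19 lower). The share of mapped reads outside annotated genes was 28.5% ± 1.55 (SD, n = 6) with betamethasone and 31.4% ± 3.31 with saline (exact permutation p = 0.0823, adjusted p = 0.494 over 24 tests), and the share of unmapped reads was 12.1% ± 0.491 and 13.8% ± 1.80 (exact permutation p = 0.0173, adjusted p = 0.208). With the former share as a covariate 14 genes passed, 9 of them among the 48. All 48 kept their direction and an unadjusted p under 0.05 in that fit, with a median of 97.0% of their log2 change, while their median SE rose from 0.124 to 0.147.

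The effects in different regions were then compared. Of 14137 genes tested in all 4 regions, 36.5% had the same direction in every region, against 12.5% for independent signs; 19 genes were higher and 51 lower at an unadjusted p under 0.05 in all 4, where independent lists would give 0.0315 and 0.0580. Libraries of one animal in several regions would raise these values without any effect of treatment. The labels do not name animals, but title numbers run in parallel over the regions, and of 60 pairs of libraries in 10 sets matched by them across the 4 regions 55 had deviations from their group means that correlated above 0.1. With treatment permuted jointly over these sets, 34.2% of genes had 1 direction in all 4 regions in the real grouping, against a mean of 29.5% (exact permutation p = 0.248; 210 splits). The numbers of genes in all 4 lists were not set against this grouping. Of the genes called in ACC, 35 of 46 had the same direction in aDG, 41 of 46 in pDG and 40 of 47 in BLA, while over all genes 58.9%, 68.2% and 63.5% shared their direction with ACC.

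Across genes, which are not independent replicates, log2 changes of aDG and pDG correlated with a Pearson's r of 0.69 and a Spearman's rho of 0.56. With treatment permuted jointly over the title-number pairs the mean r was 0.30 (permutation p = 0.07, adjusted 0.07, and 0.16 for rho, adjusted 0.16; 6 relations in the family). The covariance was 0.0611, against a mean of 0.0266 in the permuted sets. For the other pairs, with regions permuted separately, which gives too small a p where animals are shared, r and rho were 0.29 and 0.27 for aDG with BLA (permutation p = 0.02 and 0.05, adjusted 0.03 and 0.075) and 0.30 and 0.27 for aDG with ACC (p = 0.06 and 0.13, adjusted 0.07 and 0.156). They were 0.39 and 0.46 for pDG with BLA, 0.34 and 0.47 for pDG with ACC (permutation p = 0.02 throughout, adjusted 0.03 for r and 0.04 for rho) and 0.40 and 0.41 for BLA with ACC (permutation p = 0.01 and 0.02, adjusted 0.03 and 0.04). Among genes with a mean CPM of at least 5 the adjusted permutation p of rho was 0.06 for pDG with BLA, 0.06 for pDG with ACC, 0.10 for BLA with ACC and 0.12 for aDG with BLA, so no rho passed, while r passed for the same 4 pairs (adjusted 0.03 to 0.045). With treatment permuted jointly over the 10 sets, r of mean log2 CPM differences was 0.28 for aDG with BLA (exact permutation p = 0.371, adjusted 0.446), 0.31 for aDG with ACC (p = 0.690, adjusted 0.690) and 0.45 for pDG with BLA (p = 0.0810, adjusted 0.162). It was 0.42 for pDG with ACC (exact permutation p = 0.205, adjusted 0.307), 0.47 for BLA with ACC (p = 0.00952, adjusted 0.0571) and 0.61 for aDG with pDG (p = 0.0571, adjusted 0.162), so no pair passed after adjustment over 6. All values with aDG or BLA include aDG saline replicate 5, which lies with BLA, and BLA saline replicate 5. They were not repeated without these libraries.

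A difference of the treatment effect between regions was tested directly. The main fit treats libraries as independent, which can give too large a p where regions share animals. In edgeR 0 of 15257 genes passed the joint test over the 4 regions (lowest adjusted p 0.142, 470 genes at an unadjusted p under 0.05, 2 genes in DESeq2). One identifier passed between aDG and ACC, ENSMFAG00000045090, which fell in ACC (log2 change -0.69) and stood at 0.06 ± 0.12 (SE) in aDG (interaction 0.74 on the log2 scale, edgeR adjusted p = 0.0441). With aDG saline replicate 5 and BLA saline replicate 5 both left out the same interaction was 0.69 (edgeR adjusted p = 0.158) and 0 genes passed. With the title-number set over 4 regions as replicate block it passed both this test (edgeR adjusted p = 0.00442) and the joint test (0.0246, 1 gene, 855 at an unadjusted p under 0.05). Between the other pairs 0 genes passed in edgeR, with 80 (aDG and pDG), 778 (aDG and BLA), 525 (pDG and BLA), 412 (pDG and ACC) and 778 (BLA and ACC) at an unadjusted p under 0.05; DESeq2, run for aDG and pDG, called 0.

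The last question was how the regions differed without treatment, in the 24 saline libraries (14879 genes tested). Between the dentate gyrus and ACC 6004 genes passed, 2961 higher and 3043 lower in the dentate gyrus, and 1767 of these differed at least 2-fold. ENSMFAG00000039481 averaged 35.5 ± 20.6 CPM in aDG and 41.4 ± 28.2 in pDG (SD, n = 6 each) against 0.106 ± 0.0838 in ACC, a log2 difference of 8.41 ± 0.83 (SE; edgeR adjusted p = 2.62e-08). ENSMFAG00000039111 was also higher (6.87 ± 1.55, edgeR adjusted p = 0.00107) but ranged from 0.214 to 4425 CPM within the dentate gyrus and gave 5.95 without its highest library, pDG saline replicate 5. ENSMFAG00000040218 averaged 168.6 ± 26.9 CPM in ACC against 0.719 ± 0.589 in aDG and 0.679 ± 1.23 in pDG (log2 difference -8.05 ± 0.57, edgeR adjusted p = 1.38e-10; -8.93 without pDG saline replicate 3). ENSMFAG00000038207 averaged 66.3 ± 16.2 CPM in ACC against 1.07 ± 2.18 in aDG and 0.0336 ± 0.0247 in pDG (-8.41 ± 0.79, edgeR adjusted p = 1.25e-08; -9.67 without aDG saline replicate 5).

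Between the dentate gyrus and BLA 2427 genes passed, 1128 higher and 1299 lower in the dentate gyrus, 926 of them at least 2-fold. ENSMFAG00000039481 averaged 0.0158 ± 0.0288 CPM in BLA (log2 difference 10.94 ± 1.003, SE; edgeR adjusted p = 4.66e-07; 12.42 without BLA saline replicate 5), and ENSMFAG00000039111 1.65 ± 3.33 CPM (8.25 ± 1.67, edgeR adjusted p = 0.00116; 10.51 without BLA saline replicate 3 and 7.34 without pDG saline replicate 5). ENSMFAG00000042632 averaged 47.2 ± 26.5 CPM in BLA, 7.19 ± 16.8 in aDG (41.5 in replicate 5) and 0.178 ± 0.115 in pDG (-5.38 ± 0.94, edgeR adjusted p = 0.000291), and ENSMFAG00000039808 21.4 ± 12.1, 2.53 ± 5.44 (13.6 in aDG replicate 5) and 0.174 ± 0.130 CPM (-4.95 ± 0.85, edgeR adjusted p = 0.000227). BLA saline replicate 5 held 1.43 CPM of the former (34.7 to 68.96 in the other 5) and 0.0892 of the latter (17.8 to 33.97), and also little ENSMFAG00000038207 (0.0535 against 3.34 to 9.53). Without aDG saline replicate 5 the 2 differences were -7.65 and -6.50, and with that library and BLA saline replicate 5 both left out 3293 genes passed.

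Between BLA and ACC 4560 genes passed, 2283 higher and 2277 lower in BLA, 1549 of them at least 2-fold. ENSMFAG00000030844 averaged 96.2 ± 44.9 CPM in BLA and 0.975 ± 0.207 in ACC (SD, n = 6 each; log2 difference 6.63 ± 0.58, SE; edgeR adjusted p = 1.22e-08). ENSMFAG00000044088 was higher in BLA by 6.11 on the log2 scale, which rested on BLA saline replicate 5 (86.1 CPM, the other 5 at 0.533 to 2.21) and was 2.49 without it. ENSMFAG00000000951 averaged 83.7 ± 41.9 CPM in ACC and 0.367 ± 0.189 in BLA (-7.85 ± 1.19, edgeR adjusted p = 2.55e-05), and ENSMFAG00000041678 41.4 ± 23.7 and 0.229 ± 0.161 CPM (-7.48 ± 0.61, edgeR adjusted p = 5.31e-09).

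Between the anterior and posterior dentate gyrus 0 genes passed in edgeR (lowest adjusted p 0.0542, 654 genes at an unadjusted p under 0.05, 19 in DESeq2), while in the betamethasone libraries 401 passed (215 higher, 186 lower in aDG). These 2 counts do not test an effect of treatment, and the direct interaction of aDG and pDG gave 0 genes. Only the saline fit held aDG saline replicate 5 and BLA saline replicate 5. In the saline libraries, with the title-number pair as replicate block, 31 genes passed, 16 higher and 15 lower in aDG, and without pair 5, which holds the aDG library that lies with BLA, 840 passed (519 higher, 321 lower). With the set over 4 regions as replicate block 2 passed. The unblocked count was 6 without pDG saline replicate 5, 5 without BLA saline replicate 5, 2 without BLA saline replicate 2 and 1 without pDG saline replicate 2, BLA saline replicate 4 or ACC saline replicate 6. It stayed at 0 in the other fits with 1 library left out, including that without aDG saline replicate 5.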

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

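Chosen only after the result was seen were the tests of a wrong tissue or label and of a swap, and the regroupings of libraries for all comparisons but those of the dentate gyrus with ACC and of BLA with ACC. The joint permutation and the splits of the 10 sets were planned after the correlations of effects and the blocked calls were seen, but before their own results were. Extreme libraries were sought in 80 sets of values, and 8 were found, where chance gives about 1 in 20.

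The library labelled aDG saline replicate 5 lay at 1.002 on the axis from pDG (0) to BLA (1), and the nearest aDG saline library at 0.211. A mixture with dentate gyrus tissue would leave pDG-specific genes at a substantial level, but their median was 3.78% of that in the other aDG libraries, below the 5.89% seen in BLA libraries. A swap within these libraries would need a BLA library that holds dentate gyrus tissue. The lowest BLA position was 0.954, in BLA saline replicate 5 of the same title-number set, where BLA-specific genes were low too (22.4%), but pDG-specific genes stood at 6.56% of their aDG level, against 30.2% or more in the other aDG libraries. BLA tissue or a BLA label in place of aDG (position 1.002) stays open as a candidate explanation, since the test cannot separate the dissection from the labelling, and no biological explanation was tested.

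In a further pattern, treatment effects recurred across regions, and animals that gave several regions may carry their chance differences into each. Among all 462 splits of the 11 dentate gyrus pairs, 29 gave a covariance of aDG and pDG effects as large as the real one (one-sided exact permutation p = 0.0628, and 0.0390 for r), and in the 9 pairs that correlate 6 of 84 did (p = 0.0714, and 0.0119 for r). Over the 210 splits of the 10 sets across 4 regions the covariance gave an exact permutation p = 0.257 for aDG and BLA, 0.410 for aDG and ACC and 0.0810 for pDG and ACC, and the share of genes with 1 direction in all 4 regions p = 0.248, so shared animals stay open as a source of the recurrence there. For pDG and BLA the covariance gave a permutation p = 0.0429 but r gave 0.0810, which decides nothing, and for BLA and ACC both gave 0.00952, which argues against shared animals as the whole source in that pair, though adjusted over 6 pairs it is 0.0571. The tests with aDG or BLA kept aDG saline replicate 5, which lies with BLA, and BLA saline replicate 5, with many genes of its own. Both are in the same set, and their own differences enter the real and the permuted effects. No run left that set out, so how far these p-values rest on it is not known. An effect of betamethasone in several regions also stays open.

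Another pattern is the set of 48 genes called in ACC, where the share of mapped reads outside annotated genes was 28.5% with betamethasone and 31.4% with saline, a difference that did not pass its test. If RNA quality measured by this share were the cause, the slopes of these genes on it in the other 3 regions would predict most of their change. They predicted a median of 3.38% of it (2.35% to 4.77% with each region left out), which argues against this share as the cause. With the share as covariate all 48 kept their direction and a median of 97.0% of their log2 change (quartiles 91.3% and 108.4%), while their median SE rose from 0.124 to 0.147, and what ended the calls was not tested further. Chance in the grouping is made unlikely by the regrouping below. An effect of betamethasone stays open as a hypothesis, as do differences in tissue makeup, which were not tested. The share of unmapped reads in ACC was 12.1% with betamethasone and 13.8% with saline (exact permutation p = 0.0173, adjusted p = 0.208). It was not used as a predictor or covariate, so RNA quality in that respect stays open too.

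The libraries were regrouped at random, with 100 splits for each comparison and the real one counted. Only the real split reached its count for ACC (48 genes, as many in 1 split, highest other 1), which makes chance unlikely. The same held for the dentate gyrus against BLA (2427, as many in 1, highest other 825), the dentate gyrus against ACC (6004, 1 and 1) and BLA against ACC (4560, 1 and 3135). For aDG 2 splits gave as many (1 gene, highest other 1), and for pDG 3 did (1 gene, highest other 11). These shares are not adjusted over the comparisons, and both calls were lost without some single libraries. Chance is therefore not excluded in aDG or pDG. A pDG split with 11 genes, where 2 of the other 99 had any, may reflect a structure of those libraries beyond treatment, and which libraries it grouped was not examined. For the gene that differed between aDG and ACC, 7 of 100 splits gave as many and the highest other gave 3, so chance is not excluded. Those splits ignore the title-number sets. With the set as replicate block its adjusted p fell to 0.00442, and 5 of 100 splits of the sets gave as many (highest other 1), as did 6 of 100 for the 1 gene in the blocked joint test (highest other 1), so chance is not excluded there either. Where the real count was 0, all 100 splits gave as many. The highest other was then 13 in BLA, 32 for the joint test over regions and 3 for aDG against pDG in saline. For differences of the treatment effect it was 14 (aDG and pDG), 391 (aDG and BLA), 103 (pDG and BLA), 0 (pDG and ACC) and 92 (BLA and ACC). Splits with a call numbered 41 for aDG and BLA, 31 for pDG and BLA and 35 for BLA and ACC. For the pairs without BLA they numbered 5 (aDG and pDG), 6 (aDG and ACC) and 0 (pDG and ACC). The calls in pairs with BLA may reflect a structure of the BLA libraries other than treatment. Whether BLA saline replicate 5 carried them was not examined.

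The other extreme libraries are given as values. In aDG betamethasone replicate 3 the share of mapped reads outside annotated genes was 28.2% (nearest 32.6%) and the position on the pDG to BLA axis 0.203 (nearest 0.122). In ACC the share of unmapped reads was 13.1% in betamethasone replicate 2 (nearest 12.1%), and the share of reads in the 50 most abundant genes was 9.62% in betamethasone replicate 6 (nearest 9.28%). In aDG saline replicate 3 the opposite strand took 1.90% of reads (nearest 1.63%), and in pDG saline replicate 6 unmapped reads took 31.4% (nearest 14.7%). BLA saline replicate 1 held 24.4 CPM of ENSMFAG00000042278 (nearest 31.6). The treatment effect on ENSMFAG00000045090 differed between aDG and ACC by 0.74 on the log2 scale (edgeR adjusted p = 0.0441).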

How the results depend on the processing

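Chosen only after the data were seen were the covariate for reads outside annotated genes, repeated identifiers kept apart, the joint removal of 2 libraries the block without pair 5 and the block of sets over 4 regions. Of 837 alternative values 758 kept their direction and side of the threshold (named identifiers) or stayed within 1.5 times (counts). Of the 591 for named identifiers 564 did, and 0 reversed, a label that counts could not receive. The rest were counts, of which 52 moved, and a count that stayed at 0 was held as kept. For the treatment counts of aDG, pDG, BLA and ACC (1, 1, 0 and 48), DESeq2 gave 36, 82, 73 and 557, limma voom 4, 2, 0 and 189, an adjusted p threshold of 0.1 gave 3, 2, 0 and 192, and the fit of all 44 libraries 9, 4, 1 and 27. In ACC 1 surrogate variable gave 371 and the covariate 14. All 48 ACC genes were among the calls of DESeq2, limma voom and the surrogate variable fit, and 9 among those with the covariate. Without 1 library the counts ranged from 0 to 2 (aDG), 0 to 7 (pDG), 0 to 0 (BLA), 3 to 206 (ACC), 0 to 6 (aDG against pDG in saline), 2002 to 3022 (dentate gyrus against BLA), 5227 to 6511 (dentate gyrus against ACC) and 3947 to 5007 (BLA against ACC). The joint test over regions gave 2 genes in DESeq2, and the gene that differed between aDG and ACC was lost (0) with 2 libraries left out. For aDG against pDG in saline (0), DESeq2 gave 19, betamethasone libraries 401, the replicate block 31 and the block without pair 5 840; for the dentate gyrus against BLA betamethasone libraries gave 4008. The pair block was run for 1 other result, the interaction of aDG and pDG, where it gave 0 genes too, and there title numbers are only a hint, since 9 of 11 aDG libraries correlated best with their own number. With the set over 4 regions as replicate block, a hint likewise (55 of 60 matched pairs were the closest), 3528 genes passed for the dentate gyrus against BLA (2357 of the 2427 among them), 7757 for the dentate gyrus against ACC (5994 of the 6004), 6373 for BLA against ACC (4513 of the 4560), 2 for aDG against pDG and 1 in the joint test over regions. For differences of the treatment effect it gave 1 (aDG and ACC) and 0 for each of the other 5 pairs. Apart from the threshold and the fewer libraries in a fit, the cause was not tested. Symbol-based lists were not run. Depth limits genes with few reads, and at the spread of these libraries 1.5-fold changes were found in 14.9% (BLA) to 58.2% (ACC) of simulated cases.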

Other observations

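The test below was chosen after the levels were seen. ENSMFAG00000045861, the identifier that separated all libraries by treatment, differed among saline libraries too. In aDG saline it ranged from 0.0351 to 0.986 CPM, a ratio of 28.1, with the lowest value, in the library that lies with BLA (replicate 5), resting on 1 read. Without that library the ratio was 6.58. Over the 6 saline title-number pairs its log2 levels in aDG and pDG correlated (Pearson's r = 0.93, two-sided exact permutation p = 0.00278, adjusted 0.00556; Spearman's rho = 0.94, two-sided exact permutation p = 0.0167, adjusted 0.0167), and r was 0.73 without the 2 pairs farthest from the median in aDG. Without pair 5 the correlation did not pass (r = 0.79, two-sided exact permutation p = 0.117, adjusted 0.117; rho = 0.90, two-sided exact permutation p = 0.0833, adjusted 0.117). A level set by the animal stays open as a hypothesis that rests in part on pair 5 (rho 0.94 with it), and a shared batch of the paired libraries was not tested.

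BLA saline replicate 5 held 149 genes at least 4-fold above every other BLA library, 146 of which were higher in it than in any of the 44 libraries, and 126 genes at least 4-fold below every other BLA library. Counted the same way within their own regions, pDG betamethasone replicate 1 held 88 genes above and aDG betamethasone replicate 4 held 34. These 2 libraries carry different title numbers, and the deviations of the aDG library correlated best with those of the pDG library (r = 0.52 across genes, against -0.06 for its own number). In turn, aDG betamethasone replicate 1 correlated best with pDG betamethasone replicate 4 (r = 0.246, against 0.045 for its own number). Against BLA and ACC, however, each of these aDG and pDG libraries was closest to the library of its own set. An exchange of libraries was not tested.

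Reads on the strand opposite to annotated genes were tested for treatment in the same way. In edgeR 0 genes passed in aDG (of 4634), pDG (of 4288), BLA (of 5531) or ACC (of 4928), and 8.24%, 4.85%, 9.22% and 6.23% of genes had an unadjusted p under 0.05. No other tool was run on them.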
